A study of Mus musculus with 48 samples.

How the data were processed

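Gastrocnemius muscle, a mixed but mostly fast-twitch muscle of the calf, was profiled by RNA-seq in 48 mice, with 1 library per mouse. Perfluorooctane sulfonate (PFOS) is a persistent fluorinated surfactant. It was given by oral gavage at 0, 1 or 10 mg/kg/day for 21 days to males and females of 2 genotypes. hCYP2B6-Tg mice carry the human cytochrome P450 gene CYP2B6, and Cyp2b-null mice lack mouse genes of the Cyp2b family. Genotype, sex and dose gave 12 groups of 3 to 5 mice, and the labels number the mice within each group. Sex and genotype together are called the 4 strata.

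RNA was extracted with TRIzol and messenger RNA was purified from total RNA by the sequencing provider, per the labels. The extraction text of the labels names another tissue, liver, while the tissue field of every sample names gastrocnemius. The muscle and liver transcripts in the counts are given with the results. The authors deposited 1 table of raw read counts for 54532 mouse genes, with gene symbols and coordinates. HISAT2 and the genome build GRCm39 are named in the submitters' processing notes, without version or role. The counting program, its annotation and whether it used strand are not given in the sources used here. The coordinates in the deposited count table belong to GRCm38, not GRCm39. Of its gene identifiers 54495 are also in GENCODE vM21, and 53585 of these (98.3%) have the same start and end there. Coordinates below are therefore GRCm38, as in the table. Because the use of strand is not given, reads of overlapping or antisense genes cannot be told apart. Families of near-identical genes, such as the haemoglobins, glutathione S-transferases, class I histocompatibility genes and ribosomal proteins, are uncertain at the level of the single gene.

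Total counts per library ran from 11571142 to 19921061, with a median of 14420691. Statements about absent transcripts rest on a floor of 3 counts, which covers counting error only. All 48 columns were matched to a sample by name. Counts of 73 pairs of mice within groups were compared, and the lowest chi-square per degree of freedom was 7.24, so no library was taken to be a copy of another.

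Genes were filtered with filterByExpr of edgeR (version 4.0.16, in R 4.3.3), which left 15583 genes, and library sizes were scaled with TMM. Negative binomial models with 1 coefficient per group were fitted to the deposited counts with edgeR's quasi-likelihood functions (36 residual degrees of freedom, biological coefficient of variation 23.5%). Each contrast was tested with glmQLFTest, two-sided, and p was adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are given as log2 fold change ± standard error, and an average over strata weights the 4 strata equally. Levels are CPM computed from the deposited counts on TMM-scaled library sizes, as mean ± SD. The 15 contrasts were 10 against 0, 1 against 0 and 10 against 1 mg/kg/day averaged over strata, 10 and 1 against 0 within each stratum, the difference between the sexes and between the genotypes in the effect of 10 mg/kg/day, and the genotypes and sexes at 0 mg/kg/day. With 3 to 5 mice per group, the p-values measure the spread between mice.

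Gene lists, 41 in number and each with at least 5 tested members, covered mitochondrial and fuel metabolism, protein turnover, contractile proteins, stress responses and markers of other cell types. They were tested with camera at the preset inter-gene correlation of 0.01, adjusted over lists, and again with a correlation estimated from the data (limma 3.58.1). Library measures, such as the mean log2 CPM of a marker list, were compared between doses with two-sided permutation tests of 100000 permutations within strata, adjusted over 22 tests.

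Genes are named by a rule. For 10 against 0 mg/kg/day averaged over strata it takes the 12 largest rises and the 12 largest falls among genes that passed, had an average log2 CPM of at least 1 and had the same sign in all 4 strata. For other contrasts it takes 5 and 5 that passed at that level. From each list it takes up to 4 members that passed with the smallest p, and a set of muscle genes (among them Pdk4, Ucp3, Angptl4, Ppargc1a, Cpt1b, Fgf21, Fbxo32, Trim63, Myh7 and Myh4), the deleted Cyp2b genes, sex-specific genes and liver markers are read in any case. Predicted genes without a proper symbol were counted but not named. Some genes that the rule takes are not reported here, and they were left out of the values per gene and of the search for single libraries that stood apart. The contrasts, tests, lists and this rule were set before the data were examined.

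Settings tried beside this, fixed in advance, were DESeq2 size factors in edgeR, no filter on low counts, a stricter filter (CPM of at least 1 in 16 libraries), the mouse number as a block, library sizes without mitochondrial genes and the 20 most abundant genes, DESeq2 (version 1.42.0), limma voom with sample quality weights, a fit of the compared groups alone and leaving out each library in turn. Chosen after the data were seen were a fit without 6 libraries with lymphoid or liver transcripts, fits with the adipocyte or the slow fibre markers as a covariate, library totals without scaling factors, and the genotype difference within each sex.

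The procedure was tested on simulated counts for 15583 genes at the means, dispersions and library sizes of the data. For 10 against 0 mg/kg/day averaged over strata, 62% of 100 genes changed 1.5-fold and 84% of 100 changed 2-fold were recovered, with 5 false calls. For 1 against 0 mg/kg/day averaged over strata these were 63% and 82%, with 12 false calls. Within a stratum, 21 to 30% and 64 to 68% were recovered for 10 against 0, and 28 to 29% and 42 to 49% for 1 against 0. With no simulated change, 0 genes were called in every contrast and 0 of 41 lists for 10 against 0 averaged over strata. The simulated genes varied independently of each other, so these runs cannot show how often genes or lists that vary together are called falsely.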

Results

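Transcripts of gastrocnemius muscle were counted in 48 mice after 21 days of PFOS at 0, 1 or 10 mg/kg/day, a study whose stated subject was mitochondrial metabolism in skeletal muscle. There were 17 mice at 0, 16 at 1 and 15 at 10 mg/kg/day. Each of the 12 groups held 4 mice, except 5 hCYP2B6-Tg males at 0 mg/kg/day and 3 Cyp2b-null males at 10 mg/kg/day. Total counts per library were 11571142 to 19921061. Within every stratum the library numbers in the labels rose from dose to dose without overlap. Handling that differed between the doses of a stratum can therefore not be separated from dose. Across strata the numbers overlapped: 6 libraries of Cyp2b-null males at 0 or 1 mg/kg/day had higher numbers than 11 libraries at 10 mg/kg/day of the other strata. Mitochondrially encoded transcripts took 9.745 to 12.55% of counts in these 6 and 5.533 to 9.782% in the 11.

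The sex labels were borne out in all 48 libraries. Xist, the RNA that silences an X chromosome, had 1596 to 4257 counts in females and 0 to 6 in males, and the Y-linked gene Ddx3y had 0 counts in females and 1134 to 3029 in males. Genotype could not be checked, because the deleted mouse genes were nearly silent in this muscle. Cyp2b9 had 10 counts in all, from 1 Cyp2b-null library, Cyp2b10 had 5, also from 1 Cyp2b-null library, and Cyp2b13 had 0, below the floor of 3 counts. The counts of Cyp2b9 and Cyp2b10 lie above that floor in 2 libraries labelled Cyp2b-null, of which the one with Cyp2b9 is also the one with 27859 counts of Alb. All hCYP2B6-Tg libraries together had 0 counts of Cyp2b9, Cyp2b10 and Cyp2b13. Since the floor covers counting error only, these few counts do not decide on a genotype label. Human CYP2B6 was not analysed here. The fast myosin gene Myh4 averaged 68030 ± 8677 CPM (SD, n = 17) without PFOS. Alb, the liver-made plasma protein albumin, had at most 74 counts in any female library, and its highest count, 27859, was in Cyp2b-null male replicate 2 at 1 mg/kg/day. Glycam1, a gene of lymph node vessels, marked 5 other libraries. It had 312 counts in hCYP2B6-Tg female replicate 4 at 0 mg/kg/day. At 10 mg/kg/day it had 615 in hCYP2B6-Tg female replicate 1, 790 in Cyp2b-null female replicate 3, 71 in hCYP2B6-Tg male replicate 3 and 41 in Cyp2b-null male replicate 3. Counts of genes are given below also without these 6 libraries, an alternative chosen after the data were seen.

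The make-up of the libraries differed at 10 mg/kg/day. Mitochondrially encoded transcripts took 10.6 ± 1.33% of counts at 0 mg/kg/day (SD, n = 17) and 7.66 ± 1.27% at 10 mg/kg/day (n = 15). The 20 most abundant genes took 36.3 ± 1.34% and 30.5 ± 3.22% (permutation p = 1e-05 for both, the smallest that 100000 permutations can give, adjusted p = 7.33e-05). More genes were detected at 10 mg/kg/day (20280 ± 712 against 19260 ± 513, permutation p = 0.00013, adjusted p = 0.000715), where total counts were 15270000 ± 1840000 against 14090000 ± 1145000 (permutation p = 0.0387, adjusted p = 0.122). The mean log2 CPM of adipocyte markers was 2.30 ± 0.97 at 0 and 3.93 ± 1.22 at 10 mg/kg/day (permutation p = 0.00056, adjusted p = 0.00246). That of liver markers was -1.25 ± 0.72 and -0.28 ± 0.75 (permutation p = 0.00206, adjusted p = 0.00755). Slow fibre genes (permutation p = 0.136), nerve markers (0.116), tendon markers (0.381) and neutrophil and lymphocyte markers (0.267) did not pass. At 1 mg/kg/day the lowest p among the same 11 measures was 0.181, for the mitochondrial share (10.0 ± 1.25%, n = 16).

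**Figure D1:**
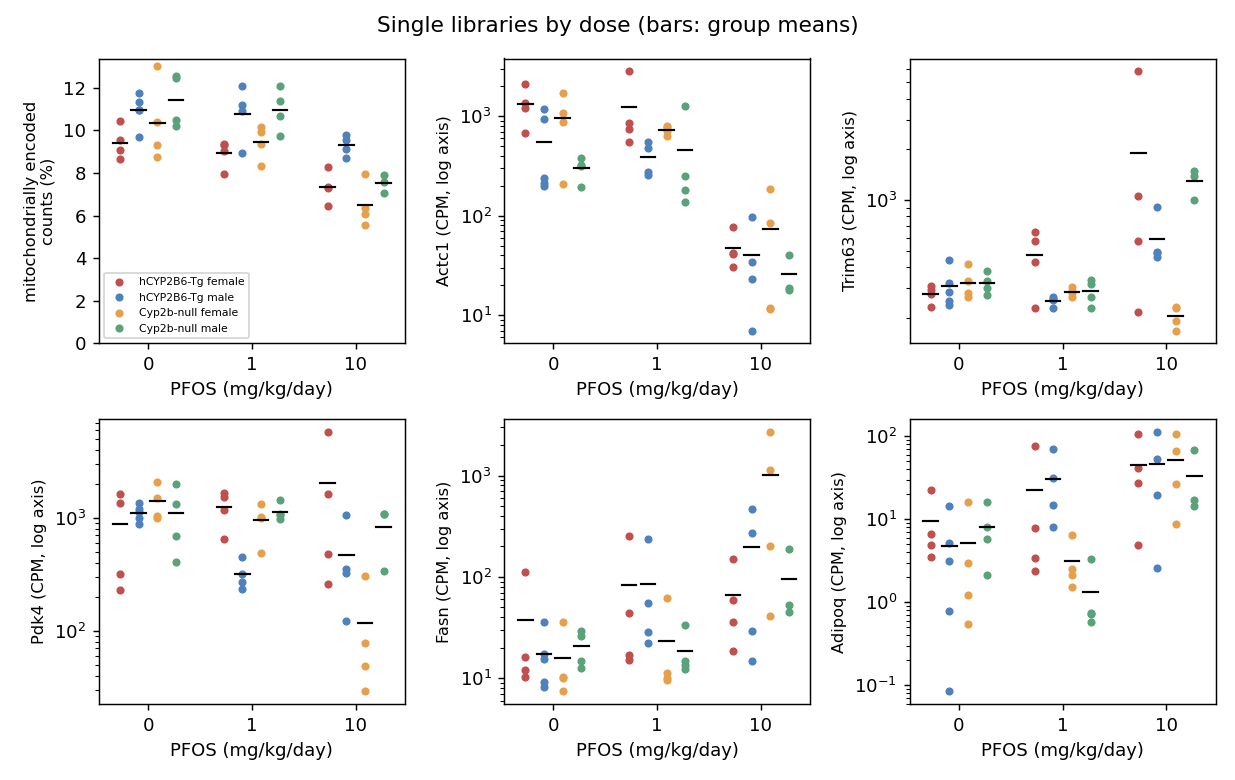
Each point is 1 library, with the 4 strata in color and bars at group means, for the share of mitochondrially encoded counts (%) and for Actc1, Trim63, Pdk4, Fasn and Adipoq (CPM, log axis) at 0, 1 and 10 mg/kg/day PFOS. The mitochondrial share averaged 10.6% at 0 and 7.66% at 10 mg/kg/day, and Trim63 in hCYP2B6-Tg females at 10 mg/kg/day ran from 217.1 to 5801 CPM.

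The first question was what 10 mg/kg/day did to the muscle across both sexes and genotypes. The deepest fall was in Actc1, the cardiac alpha-actin gene also used by immature muscle (ENSMUSG00000068614, chromosome 2, 114047282 to 114053548, GRCm38). It went from 775.9 ± 593 CPM (SD, n = 17) to 48.1 ± 46.9 CPM (n = 15). The log2 fold change was -3.97 ± 0.43 (edgeR adjusted p = 8.01e-10), with -4.81, -3.8, -3.72 and -3.56 in the 4 strata. Nrep, a neuronal regeneration related protein (ENSMUSG00000042834, chromosome 18, 33437019 to 33464029), fell from 129.7 ± 32.9 to 12.6 ± 10.2 CPM (-3.52 ± 0.22, adjusted p = 2.04e-15). Other large falls were in Kcng4, a potassium channel subunit (-2.72 ± 0.2), Gamt, which makes creatine (-2.56 ± 0.2), Ostn, a peptide secreted by muscle (-2.45 ± 0.31), Col3a1, a fibrillar collagen (-2.32 ± 0.21), and Aplnr, the apelin receptor (-2.09 ± 0.15). Foxo6os fell as well (-3.23 ± 0.22), though its reads cannot be told from those of the opposite strand. Among the largest rises were genes of fat cells, given below, and Car5b, a mitochondrial carbonic anhydrase (2.92 ± 0.45).

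In all, 7403 of 15583 genes passed at 10 against 0 mg/kg/day averaged over strata, 3892 higher and 3511 lower. At least 2-fold were 705 of the rises and 379 of the falls. Of those that passed, 6117 (82.6%) had the same sign in all 4 strata, a share that choosing genes by their mean over the same strata favours. Without the 6 libraries, 6132 genes passed (3304 higher, 2828 lower), and 5902 of these were also among the 7403. The split between rises and falls depended on scaling. On library totals without scaling factors the median gene shifted by 0.22, and 9162 genes passed, 7520 higher and 1642 lower (82.1% higher, against 52.6% with TMM). Changes are given here relative to TMM scaling, and lists whose direction turned on unscaled totals are named. With the preset correlation 23 of 41 lists passed camera in this contrast, and 0 did with an estimated correlation, so the counts below describe the members and not a competitive test of the list.

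Genes of oxidative phosphorylation fell together. Of 36 measured subunits of complex I, which oxidizes NADH, 34 fell and 2 did not pass (35 fell adjusted over the list alone), with a median log2 fold change of -0.54. Ndufs1, its largest subunit (ENSMUSG00000025968, chromosome 1, 63143596 to 63176833), went from 385.2 ± 40.1 to 207.6 ± 32.1 CPM (-0.9 ± 0.07, adjusted p = 2.55e-13). All 14 genes of complexes II and III with cytochrome c fell (median -0.62, the same count adjusted over the list alone), among them Uqcrc1 (-0.82 ± 0.07) and Cycs (-0.84 ± 0.08). For complex IV, 11 of 15 fell and 2 rose, led by the muscle form Cox7a1 (-1.24 ± 0.14, 89.3 to 38.2 CPM). For complex V, the ATP synthase, 13 of 14 fell, such as Atp5g3 (-0.86 ± 0.08). Adjusted over the list alone these 2 counts were the same. Of 13 proteins encoded in mitochondrial DNA, 12 fell (13 adjusted over the list alone, median -0.69). The subunit gene mt-Co1 (ENSMUSG00000064351, chromosome MT, 5328 to 6872) went from 36160 ± 4989 to 22320 ± 4334 CPM (-0.7 ± 0.07, adjusted p = 8.21e-11). Of 21 genes of the TCA cycle and pyruvate dehydrogenase, 20 fell (the same adjusted over the list alone, median -0.56), including Pdhx (-0.71 ± 0.05), Dlat (-0.83 ± 0.07) and Mdh2 (-0.72 ± 0.06). The 6 lists had camera adjusted p of 1.3e-06 or less with the preset correlation. They had adjusted p = 0.17 for 5 of them and adjusted p = 0.28 for complex IV with an estimated correlation. The medians stayed below 0 on unscaled totals, from -0.28 for complex IV to -0.48 for the mitochondrially encoded proteins.

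Genes of fuel use moved less evenly. Of 22 fatty acid oxidation enzymes 14 fell and 1 rose (median -0.3), among the falls Acads (-0.9 ± 0.08) and Hadh, both dehydrogenases of beta-oxidation. Of 24 genes of glycolysis and glycogen 16 fell and 2 rose (median -0.42), led by the muscle phosphoglycerate mutase Pgam2 (-1.27 ± 0.14, 1738 to 734.6 CPM) and the pyruvate kinase Pkm (-0.92 ± 0.11). Both counts were the same adjusted over the list alone. Targets of the PPAR receptors, sensors of fatty acids to which PFOS can bind, went both ways: 4 of 28 rose and 10 fell, also adjusted over the list alone. Their median of -0.13 had the opposite sign from the mean of 0.02 and became 0.1 on unscaled totals (camera adjusted p = 0.32 preset and adjusted p = 0.83 with an estimated correlation). Ucp3, a mitochondrial carrier induced by fatty acids, fell (-1.34 ± 0.21, adjusted p = 2.01e-06, 180.1 ± 58.6 to 77.0 ± 65.6 CPM). Pdk4, the kinase that shuts off pyruvate dehydrogenase, passed with a mean change of -1.01 ± 0.35 (adjusted p = 0.0145). It was 1.2 in hCYP2B6-Tg females and -3.6 in Cyp2b-null females, and the former was -0.17 without hCYP2B6-Tg female replicate 2 at 10 mg/kg/day. Pdk4 did not pass without the 6 libraries (-0.72) or with the adipocyte markers as a covariate (-0.5). Ppargc1a, a coactivator of mitochondrial biogenesis, fell by 0.42 ± 0.1 (adjusted p = 0.000656), and did not pass on unscaled totals (-0.22). Angptl4 (-0.2 ± 0.3, adjusted p = 0.612) and Cpt1b (-0.25 ± 0.15, adjusted p = 0.163) did not pass. Fgf21, with 25 counts over 13 libraries, was too scarce to test.

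Of 22 genes of mitochondrial biogenesis and dynamics, 14 fell and 3 rose (4 rose adjusted over the list alone, median -0.37). Among the falls were the receptor Esrra (-0.86 ± 0.08), the deacetylase Sirt3 (-0.99 ± 0.11) and the fission GTPase Dnm1l (-0.58 ± 0.04). Of 77 mitochondrial ribosomal proteins 57 fell and 3 rose (58 and 3 adjusted over the list alone). On unscaled totals 26 fell and 16 rose, with a median of -0.04 against -0.26 under TMM. Genes of mitophagy and autophagy mostly rose, 12 of 20 with 3 falls (the same adjusted over the list alone, median 0.24), such as Bnip3 (1.1 ± 0.12) and Map1lc3b (0.73 ± 0.07), while the mitophagy receptor Fundc1 fell (-0.52). The fatty acid oxidation, glycolysis, biogenesis, mitoribosome and autophagy lists passed camera with the preset correlation (highest adjusted p = 0.018). With an estimated correlation camera gave adjusted p = 0.47, 0.17, 0.17, 0.28 and 0.37. The test fry asks whether a list moved at all, not whether it moved more than other genes. In the same order fry gave adjusted p = 0.33, 0.00083, 0.036, 0.0046 and 0.0064 in hCYP2B6-Tg females. These were 0.24, 0.00087, 0.00016, 0.0037 and 0.031 in hCYP2B6-Tg males, 0.0048, 0.00075, 0.00041, 0.0029 and 0.78 in Cyp2b-null females, and 0.042, 0.021, 0.00028, 0.02 and 0.0024 in Cyp2b-null males. Mitochondrial chaperones and proteases had 7 falls and 2 rises among 14 (the same adjusted over the list alone), including Hspd1 (-0.35). Their median of -0.08 turned to 0.14 on unscaled totals (camera adjusted p = 0.11 preset).

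Genes of protein breakdown rose in the averaged comparison. Of 27 genes of muscle atrophy and targets of the FOXO transcription factors, 18 rose and 2 fell (20 and 2 adjusted over the list alone, median 0.77). Trim63, the ubiquitin ligase MuRF1 (ENSMUSG00000028834, chromosome 4, 134315120 to 134329629), rose by 1.27 ± 0.22 (adjusted p = 9.81e-06, 307.9 ± 58.4 to 980.3 ± 1404 CPM). Fbxo32, the ligase atrogin-1, rose by 1.02 ± 0.18 (adjusted p = 9.41e-06, 538.7 ± 126.1 to 1279 ± 1113 CPM). Neither had the same sign in all strata. Depp1, a FOXO target, rose by 2.63 ± 0.29. Of 37 proteasome subunits 24 rose and 4 fell (the same adjusted over the list alone), for example Psmd8 (0.9 ± 0.1) and Psmd4 (0.71 ± 0.07). Cytosolic ribosomal proteins rose as well, 70 of 81 with 2 falls (71 and 2 adjusted over the list alone), by a median of 0.34 (Rps19, 0.65 ± 0.06). Of 23 genes of the integrated stress response, 12 rose and 1 fell (15 and 1 adjusted over the list alone). Among them were Ddit4 (2.31 ± 0.32) and the asparagine synthetase Asns (1.8 ± 0.34). The translation repressor Eif4ebp1, which is not in this list, rose by 1.63 ± 0.14. Asns did not pass with the adipocyte markers as a covariate (0.47). These 4 lists passed camera with the preset correlation (adjusted p = 1.3e-06, 0.00024, 1.2e-23 and 0.011). They had adjusted p = 0.28, 0.54, 0.19 and 0.34 with an estimated correlation.

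Insulin and glucose uptake genes counted 9 rises and 2 falls among 19 (the same adjusted over the list alone, camera adjusted p = 0.02 preset and adjusted p = 0.17 with an estimated correlation). Pik3r1, a regulatory subunit of phosphoinositide 3-kinase (ENSMUSG00000041417, chromosome 13, 101680563 to 101768217), rose from 35.1 ± 7.15 to 162.3 ± 65.4 CPM (2.16 ± 0.13, adjusted p = 4.47e-16), with 2.54, 1.84, 1.74 and 2.5 in the 4 strata. Akt1 rose (1.05 ± 0.1) and Igfbp5, which binds insulin-like growth factors, fell (-1.54 ± 0.2).

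Fatty acid synthesis genes rose, 15 of 20 with 2 falls (16 and 2 adjusted over the list alone, median 1.03). Fasn, the fatty acid synthase (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547), went from 22.5 ± 24.8 to 359.8 ± 704.5 CPM (3.13 ± 0.53, adjusted p = 5.98e-06). The change was 0.8, 3.52, 5.99 and 2.2 in hCYP2B6-Tg females, hCYP2B6-Tg males, Cyp2b-null females and Cyp2b-null males. Acaca, which makes malonyl-CoA (1.78 ± 0.26), and the regulator Srebf1 (1.03 ± 0.13) rose too. With the adipocyte markers as a covariate, the median of the 19 fatty acid synthesis genes outside the adipocyte list was 0.18 in place of 1.03 and 6 rose in place of 14, with Fasn at 0.82, Acaca at 0.81 and Srebf1 at 0.74. Adipocyte markers, which muscle fibres express little, rose in 14 of 19 cases and fell in 1 (15 and 1 adjusted over the list alone, median 1.75). Within strata 12 rose in hCYP2B6-Tg males (median 2.74) and 7 rose and 1 fell in Cyp2b-null females (2.53). Only 1 rose and 1 fell in hCYP2B6-Tg females (1.2), and 1 rose and 0 fell in Cyp2b-null males (0.94). The mean log2 CPM of these markers went from 2.30 to 3.93. The adipokine Adipoq (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028) went from 6.72 ± 6.61 to 44.8 ± 38.2 CPM (2.72 ± 0.53, adjusted p = 4.52e-05). Cfd (3.14 ± 0.55), Retn (3.14 ± 0.53) and the lipid droplet protein Cidec (2.85 ± 0.54) rose similarly. For these 2 lists camera gave adjusted p = 0.001 and 0.00083 preset and adjusted p = 0.42 and 0.5 with an estimated correlation. Liver markers, of which 5 of 12 rose and 1 fell (the same adjusted over the list alone), included Cyp2e1 (2.45 ± 0.59) and the haptoglobin gene Hp (2.45 ± 0.6), which fat also expresses (camera adjusted p = 0.14 preset). Neither passed with the adipocyte markers as a covariate (0.84 and 0.51).

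Among contractile genes, 13 of 19 fast fibre genes fell and 3 rose (the same adjusted over the list alone, median -0.37). They included the calcium-binding protein Casq1 (-1.54 ± 0.14, 2620 to 938.1 CPM), the light chain Myl1 (-1.6 ± 0.15) and Myh4 (-0.58 ± 0.09, adjusted p = 1.2e-06, to 44940 ± 10330 CPM). Slow fibre genes had 2 rises and 2 falls among 18 (the same adjusted over the list alone, camera adjusted p = 0.53), and their main myosin Myh7 did not pass (1.09 ± 0.73, adjusted p = 0.22). Of 24 genes of fibroblasts and matrix 13 fell and 3 rose, led by the collagen genes Col3a1 and Col1a1 (-2.05 ± 0.27). Of tendon markers 5 of 12 fell and 0 rose, both counts also adjusted over the list alone. Neither list fell as a whole in Cyp2b-null females, where the matrix list had 2 rises, 1 fall and a median of 0.07. Its median was -0.84, -0.5 and -0.8 in hCYP2B6-Tg females, hCYP2B6-Tg males and Cyp2b-null males. The tendon median was 0.77 in Cyp2b-null females, and -0.08, -1.34 and -2.44 in the other strata in the same order. Camera gave adjusted p = 2.5e-06, 0.0021 and 0.42 for the fast fibre, matrix and tendon lists preset. These became adjusted p = 0.34, 0.59 and 0.83 with an estimated correlation. Genes of denervated or embryonic muscle went both ways, 6 of 20 up and 7 down, also adjusted over the list alone. Their median of -0.02 became 0.21 on unscaled totals (camera adjusted p = 0.3).

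Genes known as targets of the xenobiotic receptors CAR and PXR had 6 rises and 1 fall among 9 (7 and 1 adjusted over the list alone, camera adjusted p = 0.085), such as the P450 reductase Por (0.79 ± 0.12). NRF2 antioxidant genes had 13 and 2 among 27 (the same adjusted over the list alone, camera adjusted p = 0.15), with the mitochondrial superoxide dismutase Sod2 among the falls (-0.64 ± 0.06). Inflammatory and acute phase genes rose in 7 of 14 cases with 0 falls (the same adjusted over the list alone), among them Lcn2 (2.95 ± 0.44) and Il6ra (2.48 ± 0.25). Macrophage markers rose in 10 of 18 with 0 falls (11 adjusted over the list alone, but 4 rises over all genes without the 6 libraries). Camera gave adjusted p = 0.012 and 0.029 preset and adjusted p = 0.37 and 0.6 with an estimated correlation. Of 14 neutrophil and lymphocyte markers 12 rose and 1 fell, also adjusted over the list alone. Without the 6 libraries 1 rose and 2 fell (camera adjusted p = 0.3).

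**Figure D2:**
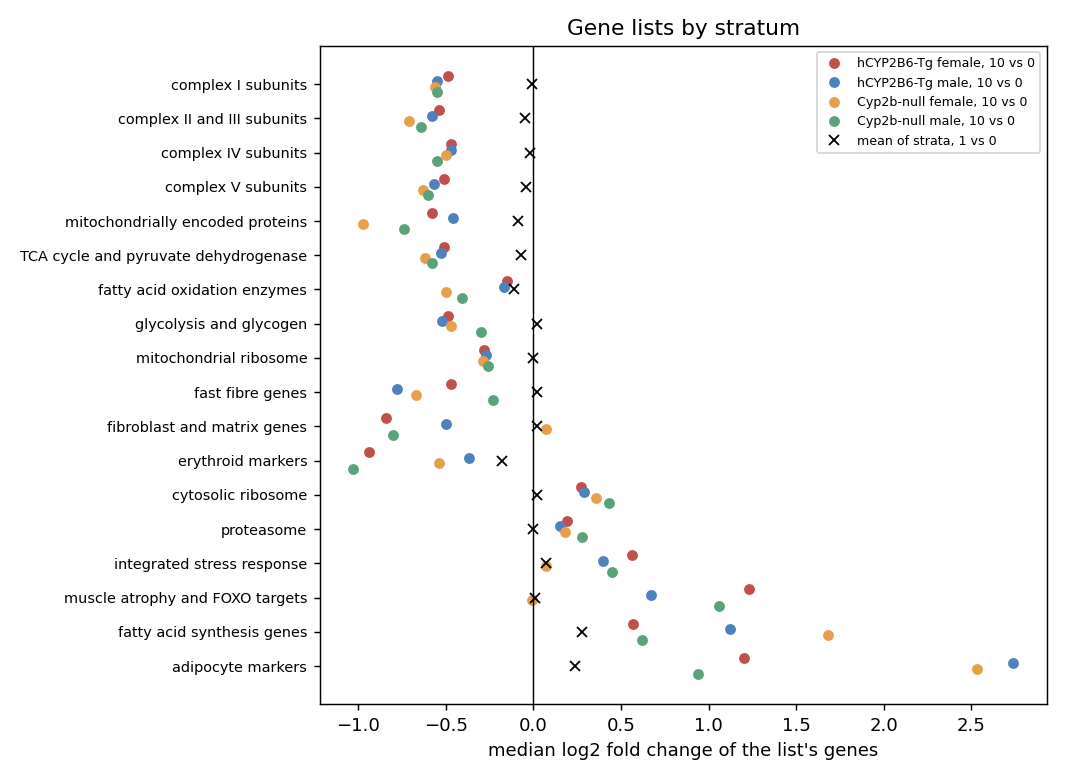
Each point is the median log2 fold change of the genes of a list at 10 against 0 mg/kg/day in 1 of the 4 strata, and crosses give the mean of the strata at 1 against 0 mg/kg/day. Complex I subunits had medians from -0.56 to -0.49 in the strata at 10 mg/kg/day, and the muscle atrophy and FOXO targets ran from -0.01 in Cyp2b-null females to 1.23 in hCYP2B6-Tg females.

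The same comparison was made within each stratum. In hCYP2B6-Tg females 4309 genes passed (2208 higher, 2101 lower). There were rises in Depp1 (4.06 ± 0.62), in Ddit4, an inhibitor of mTORC1 (4.18 ± 0.7, adjusted p = 2.82e-05), and in both ubiquitin ligases, Trim63 (2.78 ± 0.47, adjusted p = 2.94e-05) and Fbxo32 (2.31 ± 0.37, adjusted p = 1.65e-05). Trim63 there went from 278.2 ± 32.9 to 1913 ± 2615 CPM (n = 4 each), with single libraries from 217.1 to 5801 CPM. Without replicate 2 at 10 mg/kg/day the changes were smaller but still passed for Trim63 (1.15), Fbxo32 (1.38) and Ddit4 (2.49). Of 27 atrophy and FOXO genes 20 rose and 1 fell (camera adjusted p = 3.1e-09 preset, adjusted p = 0.53 with an estimated correlation). Of 36 complex I subunits 29 fell and 0 rose (1.9e-12 preset, adjusted p = 0.53 with an estimated correlation). Gamt (-3.26 ± 0.39) and Fbxl22 (-3.24 ± 0.42) were among the largest falls. The count was 4057 without the 6 libraries, 2105 when only these groups were fitted, where Trim63 did not pass (2.77), and 2796 without hCYP2B6-Tg female replicate 2 at 10 mg/kg/day.

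In hCYP2B6-Tg males 2882 genes passed (1234 higher, 1648 lower). Sarcolipin (Sln), an inhibitor of the calcium pump, rose by 4.4 ± 0.8 (adjusted p = 0.000165). Of 18 slow fibre genes 6 rose and 1 fell (camera adjusted p = 0.00046 preset, adjusted p = 0.46 with an estimated correlation). The mice were uneven: the mean log2 CPM of this list was 7.71 and 7.54 in replicates 2 and 4 at 10 mg/kg/day, but 4.7 and 5.64 in replicates 1 and 3. Without PFOS it already ran from 2.09 in hCYP2B6-Tg male replicate 4 to 7.88 in Cyp2b-null male replicate 3. Of 19 adipocyte markers 12 rose and 0 fell (camera adjusted p = 3.5e-05 preset, adjusted p = 0.39 with an estimated correlation). Complex I subunits fell in 30 of 36 cases, and 12 of 27 atrophy and FOXO genes rose with 1 fall (camera adjusted p = 2e-19 and 8.8e-05 preset, adjusted p = 0.27 and 0.35 with an estimated correlation). The myosin-binding protein Mybph fell by 3.07 ± 0.62, and Ucp3 changed by -1.6 (adjusted p = 0.00525), though not with the adipocyte covariate (-0.98). The total was 1508 without the 6 libraries, 1819 when only these groups were fitted, 4687 on unscaled totals, and 1390 with the adipocyte and 1716 with the slow fibre covariate. It was 1536 without replicate 3 and 1886 without replicate 2 at 10 mg/kg/day.

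In Cyp2b-null females 1979 genes passed (908 higher, 1071 lower). The lipogenic rise was the highest among the strata in value, though not tested as such. Fasn rose by 5.99 ± 1.22 (adjusted p = 0.000946), from 15.9 ± 13.4 to 1015 ± 1211 CPM (n = 4 each). Of 20 fatty acid synthesis genes 12 rose and 1 fell (camera adjusted p = 2.8e-08 preset, adjusted p = 0.17 with an estimated correlation). Pdk4 (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309) fell by 3.6 ± 0.75 (adjusted p = 0.00117), from 1402 ± 509.6 to 115.8 ± 129.5 CPM, and Ucp3 by 2.41 ± 0.44 (adjusted p = 0.000263). Trim63 (-0.66, adjusted p = 0.342) and Fbxo32 (-0.84, adjusted p = 0.113) did not pass. Of 27 atrophy and FOXO genes 4 rose and 2 fell. Of 13 mitochondrially encoded proteins 11 fell (median -0.97) and of 21 TCA cycle genes 19 fell (median -0.62). These 2 lists also passed camera with an estimated correlation (adjusted p = 0.041 and adjusted p = 0.047 with an estimated correlation), which no other list did in any stratum. The count was 834 without the 6 libraries, 644 when only these groups were fitted, 4893 on unscaled totals, 2975 by limma voom and 1082 with the adipocyte covariate. It was 859 without replicate 3 and 1170 without replicate 1 at 10 mg/kg/day, and 1253 without replicate 2 and 1300 without replicate 3 at 0 mg/kg/day.

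In Cyp2b-null males 2463 genes passed (1161 higher, 1302 lower). They included rises of Depp1 (3.58 ± 0.61), Ddit4 (2.97 ± 0.67), the GTPase activator Arhgap26 (3.07 ± 0.27, adjusted p = 7.52e-10), Trim63 (2.01, adjusted p = 0.00252) and Fbxo32 (1.56, adjusted p = 0.00352). Of 27 atrophy and FOXO genes 16 rose and 1 fell, and 25 of 36 complex I subunits fell (camera adjusted p = 4.1e-09 and 3.5e-16 preset, adjusted p = 0.19 and 0.27 with an estimated correlation). Slow fibre genes went the other way from hCYP2B6-Tg males, with a median of -1.74 and 0 rises and 1 fall among 18. For this list camera gave adjusted p = 0.018 preset and adjusted p = 0.72 with an estimated correlation. Nrep fell by 4.21 ± 0.5. The total was 1504 without the 6 libraries, 4133 by limma voom and 1400 without replicate 3 at 10 mg/kg/day.

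**Figure D3:**
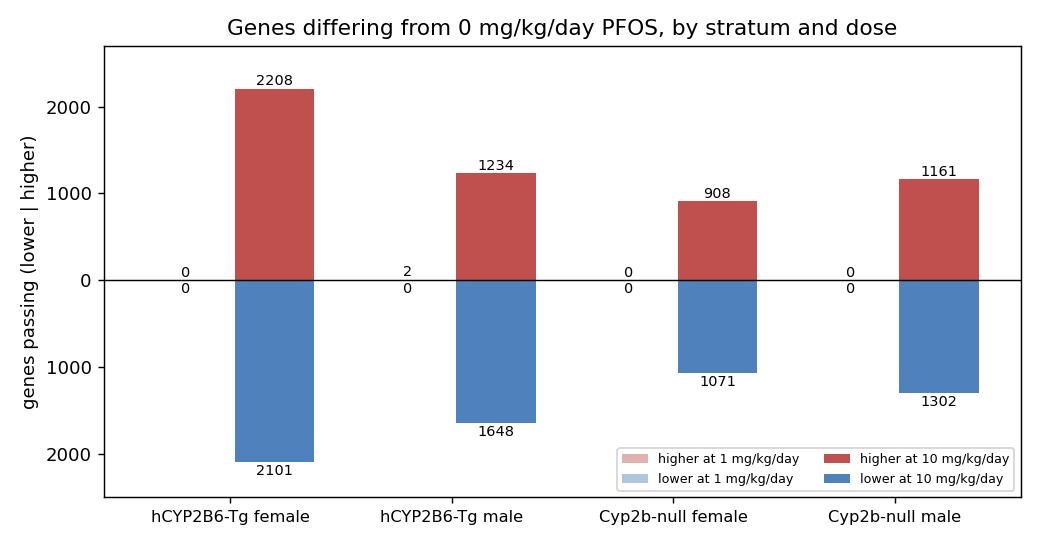
Bars give the number of genes that passed against 0 mg/kg/day PFOS (edgeR, adjusted over all genes), higher above and lower below the axis, for 1 and 10 mg/kg/day in each stratum. At 10 mg/kg/day 1979 to 4309 genes passed, and at 1 mg/kg/day 2 genes in hCYP2B6-Tg males and 0 in the other strata.

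The strata, which share no libraries, moved alike at 10 mg/kg/day. Across 15583 genes, which are not independent replicates, the log2 fold changes of 2 strata correlated with r of 0.417 (hCYP2B6-Tg and Cyp2b-null females) to 0.664 (hCYP2B6-Tg males and Cyp2b-null females). The genes that passed in both with the same sign numbered 885 to 1692 per pair, against 157 to 397 for independent lists. In addition, 634 genes passed in all 4 strata, 633 of them with the same sign (186 higher, 447 lower). At 1 mg/kg/day the same correlations lay between -0.0762 and 0.0506.

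The lower dose left little that could be detected. At 1 against 0 mg/kg/day averaged over strata, Trim63 (0.03 ± 0.22), Ucp3 (-0.21 ± 0.2), Myh4 (0 ± 0.09) and Pdk4 (-0.45 ± 0.33) all had an adjusted p of 1 in edgeR. No gene passed: the count was 0 in edgeR, 1 in DESeq2 and 0 in limma voom, with 578 genes at an unadjusted p under 0.05 in edgeR where chance gives 779. Of all lists 0 members passed adjusted over the list alone. Camera called 11 lists with the preset correlation, among them fatty acid oxidation (adjusted p = 6.8e-06, median -0.11), the TCA cycle (1.4e-05, -0.07) and fatty acid synthesis (0.0012, 0.28). All 11 had adjusted p = 0.99 with an estimated correlation. Of genes simulated with a 2-fold change at this dose 82% were recovered, so changes of that size in many genes would have been seen.

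Within strata at 1 mg/kg/day, edgeR called 0 genes in hCYP2B6-Tg females (656 at unadjusted p under 0.05, 4 by DESeq2, 46 by limma voom), 0 in Cyp2b-null females (327, 2 and 0) and 0 in Cyp2b-null males (767, 10 and 0). In hCYP2B6-Tg males it called 2 (709, 8 and 0), both low in level and outside the naming rule, so they are named after their values were seen. Fhl4, a LIM domain gene of the testis (ENSMUSG00000050035, chromosome 10, 85096287 to 85102495, adjusted p = 0.00586), had 459 counts (30.98 CPM) in replicate 4 and at most 22 in any other mouse of the stratum at 0 or 1 mg/kg/day. Ropn1l, a sperm flagellum gene (ENSMUSG00000022236, chromosome 15, 31441211 to 31453737, adjusted p = 0.047), had 178 counts (12.01 CPM) in that replicate and at most 19 in the others. Without replicate 4 at 1 mg/kg/day 0 genes passed, as without replicate 1, 3, 4 or 5 at 0 mg/kg/day. The count was 1 without replicate 2 at 0 mg/kg/day, 5 without replicate 1 or 2 and 7 without replicate 3 at 1 mg/kg/day.

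Tested directly against each other, the doses differed in 7301 genes averaged over strata (3847 higher and 3454 lower at 10 mg/kg/day), and in 5977 without the 6 libraries. Actc1 (-3.87 ± 0.43, adjusted p = 1.62e-09) and Nrep (-3.38 ± 0.22, adjusted p = 4.61e-15) were lower at 10 than at 1 mg/kg/day, as were Kcng4 (-2.79) and Ucp3 (-1.13, adjusted p = 3.61e-05). Cidec (2.74 ± 0.57), Retn (2.72 ± 0.55) and Trim63 (1.23 ± 0.22, adjusted p = 1.97e-05) were higher. Across genes the effects of the 2 doses had a covariance of 0.0205 (r = 0.277), beside 0.0151 (r = 0.485) for simulated unchanged groups that share the controls, and -0.00351 (r = -0.0363) when each dose had its own part of the controls. No effect shared between the doses was therefore detected.

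Whether males and females responded differently was tested as an interaction, and 20 genes passed (9 higher and 11 lower in males relative to females, 1490 at unadjusted p under 0.05). Amd1, which commits S-adenosylmethionine to polyamine synthesis (ENSMUSG00000075232, chromosome 10, 40287458 to 40302186), was far higher in males than females without PFOS and converged at 10 mg/kg/day. It went from 2080 ± 488.3 to 462.7 ± 286.9 CPM in hCYP2B6-Tg males and from 1980 ± 751.3 to 363.8 ± 79.9 CPM in Cyp2b-null males. In the females of these genotypes it went from 195.6 ± 20.4 to 90.0 ± 24.6 CPM and from 198.5 ± 20.6 to 141.5 ± 41.1 CPM (difference -1.5 ± 0.3, adjusted p = 0.0209). Its neighbour Cdk19, a Mediator kinase (ENSMUSG00000038481, chromosome 10, 40339564 to 40483818), went from 80.0 ± 16.1 to 32.3 ± 7.24 and from 78.0 ± 28.2 to 31.3 ± 1.32 CPM in males. In females it went from 15.1 ± 0.97 to 17.4 ± 1.71 and from 15.1 ± 1.35 to 14.8 ± 1.76 CPM (-1.4 ± 0.19, adjusted p = 0.000136). Arhgap26 rose more in males (1.5 ± 0.25, adjusted p = 0.00334) and Srebf1 less (-1.22 ± 0.25, adjusted p = 0.023). Srebf1 did not pass without hCYP2B6-Tg female replicate 1 (-1.17) or Cyp2b-null male replicate 2 or 3 at 10 mg/kg/day (both -1.21), or without Cyp2b-null male replicate 2 at 0 mg/kg/day (-1.12). Cdk19 and Arhgap26 passed in every setting run. Amd1 did not pass without the 6 libraries (-1.32), when only the compared groups were fitted (-1.5), or without Cyp2b-null male replicate 2 at 0 (-1.4) or at 10 mg/kg/day (-1.45). Tendon markers were the list with the lowest camera p (5.2e-06 preset, adjusted p = 0.99 with an estimated correlation), with 0 members passing over all genes and 9 of 12 lower adjusted over the list alone.

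The count of 20 (0.128% of genes tested) was not stable. It was 5 without the 6 libraries, 8 when only the compared groups were fitted, 13 with the mouse number as a block, 72 by DESeq2 and 187 by limma voom. It was 0.802% of genes tested without hCYP2B6-Tg female replicate 2 at 10 mg/kg/day. It was 34 without Cyp2b-null female replicate 4, 11 without Cyp2b-null male replicate 2 and 13 without Cyp2b-null male replicate 3 at 10 mg/kg/day. At 0 mg/kg/day it was 32 without Cyp2b-null male replicate 3, 6 without Cyp2b-null male replicate 2 and 13 without hCYP2B6-Tg female replicate 1.

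For the genotypes the planned tests in edgeR called no gene. The difference between hCYP2B6-Tg and Cyp2b-null mice in the effect of 10 mg/kg/day, averaged over sexes, was 1.18 for Trim63 (adjusted p = 0.459), 1.33 for Fbxo32 (adjusted p = 0.353) and 1.98 for Pdk4 (adjusted p = 0.432). In edgeR 0 genes passed (1378 at unadjusted p under 0.05, 4 by DESeq2, 0 by limma voom). Camera called slow fibre (1.3e-10, median 2.24), endothelial (2.1e-11, 0.43), mitochondrially encoded (4.2e-08, 0.36) and atrophy and FOXO genes (5.3e-06, 0.32) among others with the preset correlation. These lists had adjusted p = 0.6 to 0.61 with an estimated correlation. Adjusted over the list alone 1 slow fibre, 8 endothelial and 6 atrophy and FOXO genes were higher. Without PFOS, 0 genes differed between the genotypes in edgeR (535 at unadjusted p under 0.05, 9 by DESeq2, 5 by limma voom). Endothelial markers (camera adjusted p = 1.7e-14 preset, median -0.27) and immediate early genes (1.8e-07, -0.28) had adjusted p = 0.19 with an estimated correlation.

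Males and females without PFOS differed in 1182 genes (737 higher and 445 lower in males). Apart from Xist and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, the largest differences included Rian, an imprinted noncoding RNA (ENSMUSG00000097451, chromosome 12, 109603940 to 109661716). It was lower in males, with a log2 fold change of -1.85 ± 0.25 (adjusted p = 1.58e-06) and 10.6 ± 2.93 and 10.1 ± 2.6 CPM in males against 46.1 ± 24.4 and 30.2 ± 16.1 CPM in hCYP2B6-Tg and Cyp2b-null females. Chrna9, a nicotinic receptor subunit, was also lower in males (-2.86 ± 0.69, adjusted p = 0.00594), and Ppargc1a was higher (0.54 ± 0.14, adjusted p = 0.00947). Of 14 nerve and Schwann cell markers 5 were lower in males (10 adjusted over the list alone, median -1.07, camera adjusted p = 3.3e-05 preset, adjusted p = 0.98 with an estimated correlation). The count was 786 without Cyp2b-null male replicate 4, 760 without a filter on low counts and 2797 by limma voom.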

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

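The fits with the adipocyte or slow fibre covariate, on unscaled totals and without the 6 libraries, the genotype difference within each sex and the comparison of library numbers were chosen only after the data had been seen. The remaining tests in this part were planned.

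Single libraries stood apart from the rest of their group in 10 of 176 combinations of group and measure (16 measures), where chance gives about 1 in 20, or 5%. Liver markers had a mean log2 CPM of 7.14 in Cyp2b-null male replicate 2 at 1 mg/kg/day, the library with 27859 Alb counts, against -1.81 to -1.31 in the other mice of its group. They were at 0.63 in hCYP2B6-Tg male replicate 1 at 1 mg/kg/day, against -1.02 to -0.87. Neutrophil and lymphocyte markers were at 2.43 in hCYP2B6-Tg female replicate 4 at 0 mg/kg/day (others -1.5 to -1.08). They were at 3.03 in Cyp2b-null female replicate 3 at 10 mg/kg/day (others -1.8 to -1.41). In hCYP2B6-Tg male replicate 4 at 10 mg/kg/day both ubiquitin ligases were high, Fbxo32 at a log2 CPM of 10.78 (others 10.05 to 10.11) and Trim63 at 9.83 (others 8.84 to 8.94). Myh7 was almost lacking in hCYP2B6-Tg female replicate 1 at 0 mg/kg/day, at 0.05 against 8.13 to 9.63. Myh4 was lower in hCYP2B6-Tg female replicate 4 at 1 mg/kg/day, at 15.85 against 16.19 to 16.25. The 20 most abundant genes took 33.42% of counts in Cyp2b-null male replicate 3 at 0 mg/kg/day (others 36.3 to 36.5%). In addition, hCYP2B6-Tg female replicate 3 at 1 mg/kg/day had 12401453 total counts (others 14430705 to 14808263).

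Tests of the difference itself in the effect of 10 mg/kg/day called 20 genes between the sexes and, among females, 213 genes between the genotypes. Chance could not be excluded for the 213 (6 of 100 splits as large), and 0 genes passed when only these groups were fitted.

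The fall of oxidative phosphorylation and TCA cycle transcripts was the pattern closest to the subject of the study, and over its 98 tested nuclear genes the median log2 fold change was -0.56 (quartiles -0.66 and -0.45). Fat in the sampled muscle would dilute these transcripts. With the adipocyte markers as a covariate, however, the median was -0.43 (quartiles -0.53 and -0.3) and 87 genes still passed as lower. With the slow fibre markers as a covariate the median was -0.55 (quartiles -0.66 and -0.44). That fit could hardly remove a fall, because the slow fibre mean log2 CPM was not lower at 10 mg/kg/day (6.026 against 5.175 at 0 mg/kg/day, permutation p = 0.136). Nor does it cover shifts among fast fibre types, which stay open. Whether a few abundant transcripts set the scale cannot be decided by unscaled totals, since these totals contain such transcripts. Unscaled totals do argue against the TMM scaling factors as the whole cause. On them the median was -0.34 (quartiles -0.45 and -0.24), with 83 genes lower and 6 higher. In Cyp2b-null males a running order along the library numbers would put late libraries lower, but in 6 late libraries at 0 or 1 mg/kg/day these genes were higher than in the other 2 at 0 mg/kg/day, by a median of 0.25 (quartiles 0.14 and 0.31). This comparison is weak, because the mean log2 CPM of adipocyte markers was 3.67 and 2.46 in these 2 and 1 to 2.6 in the 6. An effect of PFOS may lie behind the pattern, but in the other strata the order of handling, and in all strata handling that differed between doses, was not tested and stays open.

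The rise of fatty acid synthesis transcripts went with adipocyte transcripts, and adipose tissue in the sampled muscle is a candidate source. Over the 19 fatty acid synthesis genes outside the adipocyte list the median was 1.03 (quartiles 0.5 and 1.59), and with the adipocyte markers as a covariate it was 0.18 (quartiles -0.01 and 0.56), where 6 genes passed as higher in place of 14. The covariate itself rose with dose, so lipogenesis in the fibres that goes along with more fat cells also stays open. The adipocyte rise itself was not brought by the libraries with lymphoid or liver transcripts: without them the median of the 19 markers was 1.62 (quartiles 1.03 and 2.52), against 1.75 with all libraries.

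Whether other groupings of the same mice give as many genes was counted with 100 random splits, or all 35 where there were fewer, the real one included. These shares were not adjusted over the contrasts, and the number of splits limits how small they can be. Without adjustment over the contrasts, chance can be excluded for 10 against 0 mg/kg/day averaged over strata (7403 genes, highest other split 2691, 1 of 100 splits as large) and for 10 against 1 (7301, highest other 1386, 1 of 100). On the same terms it can be excluded for hCYP2B6-Tg females (4309, highest other 1623, 1 of 35), Cyp2b-null females (1979, highest other 1036, 1 of 35) and Cyp2b-null males (2463, highest other 764, 1 of 35). It can also be excluded for the sexes at 0 mg/kg/day (1182, highest other 262, 1 of 100). In hCYP2B6-Tg males 2 of 100 splits were as large, so chance can again be excluded only without adjustment over the contrasts. The other split called 3129 genes against the real 2882. A split close to the real one still carries part of the dose effect, and what this one separates was not tested. For the sex difference of 20 genes 4 of 100 splits were as large. These splits moved sex labels within genotype and dose and so mixed the sexes, which differed in 1182 genes at 0 mg/kg/day. They ask whether sex mattered at all, so they cannot decide on chance for a sex difference in the effect. The number of genes was 5 without the 6 libraries and 6 without Cyp2b-null male replicate 2 at 0 mg/kg/day, and the highest other split called 1093 genes. That is many times the real count and points to a structure of the samples. What that split separates was not tested, and since sex labels moved within genotype and dose, the sex difference itself could enter it. Chance could not be excluded for the genotype difference in females (213 genes, highest other 648, 6 of 100), nor for the 2 genes at 1 mg/kg/day in hCYP2B6-Tg males (highest other 23, 6 of 100). Comparisons with a real count of 0 were matched by every split. For 1 against 0 these were the average over strata (highest other 3, 100 of 100) and the comparisons within hCYP2B6-Tg females (0, 35 of 35), Cyp2b-null females (0, 35 of 35) and Cyp2b-null males (38, 35 of 35). The others were the genotype difference averaged (124, 100 of 100) and in males (634, 100 of 100), and the genotypes at 0 mg/kg/day (2, 100 of 100). The splits with 38, 124 and 634 genes again point to a structure of the samples, and what they separate was not tested.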

How the results depend on the processing

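Every contrast was tested again under the settings fixed in advance and under the 4 chosen after the data were seen (without the 6 libraries, adipocyte covariate, slow fibre covariate, unscaled totals). Because the settings differed in how many genes they tested, the genes that passed are given here as percent of the genes tested. Whether a result moved by more than 1.5 times was judged on the number of genes, not on the percent. For 10 against 0 and 10 against 1 mg/kg/day averaged over strata the number of genes stayed within 1.5 times the reported one in all settings, while the percent with no filter on low counts was 19.24 and 19.08% in place of 47.51 and 46.85%. Of 25449 values of named genes, 24055 kept direction and call, 1342 lost the call, 42 gained it and 10 changed sign. Calls of lists by camera were compared for 10 against 0 averaged over strata with DESeq2 size factors, the replicate block, either covariate, without the 6 libraries and with an estimated correlation, and camera was not run with other filters or on unscaled totals. Of these 246 values of gene lists, 214 kept both, 30 lost the call, 2 gained it and 0 called lists changed sign. Medians of lists did change sign: liver markers from 1.81 to -0.26 with no filter, and with the adipocyte covariate liver (-1.56), slow fibre (-0.34), nerve (-0.36), cholesterol synthesis (-0.17), interferon response (-0.2), satellite cell (-0.02) and adipocyte (-0.09) genes. The covariate is the mean of the adipocyte markers, so a median near 0 for that list follows from the choice of covariate. Interferon response genes were at -0.16 and denervation genes at 0.01 without the 6 libraries, denervation genes at 0.05 under either filter setting and endothelial markers at 0.01 under the block. On unscaled totals PPAR targets (0.1), mitochondrial chaperones (0.14), denervation genes (0.21) and endothelial markers (0.2) turned. With an estimated correlation 0 of the 23 lists called for 10 against 0 averaged over strata passed. Apart from the smaller tests that come from fewer mice or fewer genes, the cause was not tested for any change given here. Depth limits the scarce transcripts, such as Fgf21 with 25 counts over all libraries.

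Results whose number of genes moved by more than 1.5 times are given by setting. Under the reported fit 27.7, 18.5, 12.7 and 15.8% of genes passed for 10 against 0 in hCYP2B6-Tg females, hCYP2B6-Tg males, Cyp2b-null females and Cyp2b-null males. For 1 against 0 in hCYP2B6-Tg males it was 0.0128%, for the sex difference 0.128%, for the genotype difference in females 1.37% and for the sexes at 0 mg/kg/day 7.59%. Fitting only the compared groups gave 15.5% for 10 against 0 in hCYP2B6-Tg females, 13.6% in hCYP2B6-Tg males and 4.76% in Cyp2b-null females. It gave 0.0523% for the sex difference, 0.00759% for 1 against 0 in hCYP2B6-Tg males and 0 for the genotype difference in females. Without the 6 libraries it was 9.68% in hCYP2B6-Tg males, 5.35% in Cyp2b-null females and 9.65% in Cyp2b-null males for 10 against 0, 0.0321% for the sex difference and 0.725% for the genotype difference in females. With the adipocyte covariate 8.92% passed in hCYP2B6-Tg males and 6.94% in Cyp2b-null females for 10 against 0, 0.314% in Cyp2b-null males for 1 against 0, and 0.815% for the genotype difference in females. The slow fibre covariate gave 11.01% for 10 against 0 in hCYP2B6-Tg males. Unscaled totals gave 30.1% in hCYP2B6-Tg males and 31.4% in Cyp2b-null females. Without the 6 libraries, with either covariate and on unscaled totals, 0.00642% (1 gene) passed for 1 against 0 in hCYP2B6-Tg males.

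DESeq2 called 0.00642% for 1 against 0 averaged over strata, and 0.0257, 0.0513, 0.0128 and 0.0642% in hCYP2B6-Tg females, hCYP2B6-Tg males, Cyp2b-null females and Cyp2b-null males. It called 0.462% for the sex difference, 0.0257% for the genotype difference, 3.47% for it in females, 0.00642% in males, and 0.0578% for the genotypes at 0 mg/kg/day. Limma voom called 19.1% in Cyp2b-null females and 26.5% in Cyp2b-null males for 10 against 0, and 0.295% in hCYP2B6-Tg females and 0 in hCYP2B6-Tg males for 1 against 0. It called 1.2% for the sex difference, 0.462% and 0.0321% for the genotype difference in females and males, and at 0 mg/kg/day 0.0321% between the genotypes and 17.9% between the sexes. With no filter on low counts 0.00566, 0.164 and 0.388% passed for 1 against 0 in hCYP2B6-Tg females, hCYP2B6-Tg males and Cyp2b-null males. There were 0.0368% for the sex difference, 0.00283% for the genotype difference, 0.363% for it in females, and at 0 mg/kg/day 0.0113% between the genotypes and 2.15% between the sexes. The stricter filter left 0 for 1 against 0 in hCYP2B6-Tg males.

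The mouse numbers did not pair the samples. Mice with the same number deviated from their group means with a mean correlation of -0.00926 (lowest -0.417, highest 0.632), against 0.00319 for different numbers, and 9 of 48 libraries correlated best with their own number. With the number as a replicate block 0.0834% passed for the sex difference, 0.905% for the genotype difference in females and 0 for 1 against 0 in hCYP2B6-Tg males. No other contrast moved by more than 1.5 times.

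With each library left out in turn, the share ran from 42.99 to 48.99% for 10 against 0 averaged over strata, from 0 to 0 for 1 against 0 and from 42.6 to 48.3% for 10 against 1. For 10 against 0 it ran from 17.9 to 30.4% in hCYP2B6-Tg females, 9.86 to 22.3% in hCYP2B6-Tg males, 5.51 to 18.5% in Cyp2b-null females and 8.98 to 13.8% in Cyp2b-null males. For 1 against 0 in the same order it ran from 0 to 0.0642, 0 to 0.0449, 0 to 0 and 0 to 0.205%. In numbers, 10 genes passed without hCYP2B6-Tg female replicate 4, and 32, 30 and 21 without Cyp2b-null male replicate 1, 3 and 4 at 1 mg/kg/day. The Cyp2b-null male counts all kept replicate 2 at 1 mg/kg/day, the library with 27859 counts of Alb. The share ran from 0.0385 to 0.802% for the sex difference, 0 to 0.0257% for the genotype difference, 0.0834 to 6.96% for it in females and 0 to 0 in males. At 0 mg/kg/day it ran from 0 to 0.0128% between the genotypes and from 5.04 to 8.47% between the sexes.

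The changes of sign were in 10 values of named genes. Without the 6 libraries, 10 against 1 averaged over strata gave -0.58 for Glycam1 and -0.16 for Ighd, and 10 against 0 in Cyp2b-null females gave -1.14 for Ighd and -0.57 for Cd79a. Leaving out Cyp2b-null female replicate 3 at 10 mg/kg/day alone gave -1.16 and -0.59 for Ighd and Cd79a, and with any other library left out they were at most 6.26 and 5.78. With the adipocyte covariate Nat8l (-0.1) and Fabp4 (-0.25) changed sign for 10 against 0 averaged over strata and Phgdh (-0.24) in Cyp2b-null females. On unscaled totals Hspd1 did in Cyp2b-null females (0.02).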

Other observations

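The genotype difference within each sex, its comparison with the averaged test, the narrowing of sex differences and the relation between ubiquitin ligase and fatty acid synthesis transcripts were tests chosen only after the result had been seen. The list counts in the next paragraphs were planned.

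Several groups of genes at 10 against 0 mg/kg/day averaged over strata have not been described above. Genes of the circadian clock had 5 rises and 1 fall among 19 (the same adjusted over the list alone, camera adjusted p = 0.17). Per2 was up by 1.01 and Cry2 by 0.88, and Bhlhe41 was down (-0.82). Immediate early genes had 10 rises and 2 falls among 23 (the same adjusted over the list alone, camera adjusted p = 0.097), Klf6 (0.64) among the rises and the phosphatase Dusp1 (-0.97) among the falls. Heat shock genes had 4 rises and 4 falls among 16 (5 and 4 adjusted over the list alone, camera adjusted p = 0.73), including Hsp90ab1 (0.36) and Hspa8 (-0.44). Cholesterol synthesis genes had 6 rises and 5 falls among 24 (the same adjusted over the list alone, camera adjusted p = 0.85), and the members went apart, with Lss at 0.67 and Dhcr7 at -0.87. Interferon response genes had 4 rises and 3 falls among 24 (1 and 1 adjusted over the list alone, camera adjusted p = 0.94).

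Markers of other cell types moved unevenly. Of 7 erythroid markers 6 fell and 0 rose (the same adjusted over the list alone, median -0.81, camera adjusted p = 0.0092 preset, adjusted p = 0.35 with an estimated correlation). Among them were Bpgm (-0.88 ± 0.12) and the haemoglobin gene Hbb-bs (-0.81 ± 0.19), whose reads may be shared with its near copy. Here the falls stayed on unscaled totals, with a median of -0.62. Endothelial markers had 4 rises and 2 falls among 18 (the same adjusted over the list alone, camera adjusted p = 0.94), and their median of -0.02 became 0.2 on unscaled totals. Smooth muscle and pericyte markers had 3 rises and 1 fall among 13 (the same adjusted over the list alone, camera adjusted p = 0.29), and nerve and Schwann cell markers 2 rises among 14 (1 adjusted over the list alone, camera adjusted p = 0.15), led by the sodium channel Scn7a (1.42 ± 0.19). Of 12 satellite cell markers 3 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.66). The adhesion molecule Cdh15 was up by 0.71 ± 0.07 and the calcitonin receptor Calcr, a marker of resting satellite cells, was down (-2.15 ± 0.31). The median of this list was 0.04 and the mean -0.14.

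A hypothesis from the strata is that genotype shapes the catabolic response of females. In females the effect of 10 mg/kg/day was higher in hCYP2B6-Tg than in Cyp2b-null mice for Fbxo32 (3.16 ± 0.51, adjusted p = 0.00185), Trim63 (3.44 ± 0.64, adjusted p = 0.00654), Ddit4 (4.96 ± 0.92, adjusted p = 0.00654), Depp1 (4.62 ± 0.83, adjusted p = 0.00646) and Pdk4 (4.8 ± 1, adjusted p = 0.0143). It was lower for Acly, which makes cytosolic acetyl-CoA (-3.51 ± 0.88, adjusted p = 0.0372). In all 213 genes (1.37% of those tested) passed, 153 higher and 60 lower (2623 at unadjusted p under 0.05). In males edgeR called 0 genes (1160 at unadjusted p under 0.05, 1 by DESeq2, 5 by limma voom). The values there were -1.08 for Trim63 (adjusted p = 0.736) and -0.49 for Fbxo32 (adjusted p = 0.877). For the planned average over sexes edgeR called 0 genes (1378 at unadjusted p under 0.05, 4 by DESeq2, 0 by limma voom). The evidence is weak: 6 of 100 splits gave as many genes, 0 passed when only these groups were fitted, and 0.725% of genes tested passed without the 6 libraries. The number of genes was 13 without replicate 2, 621 without replicate 1 and 1085 without replicate 4 of hCYP2B6-Tg females at 10 mg/kg/day, and 27, 76 and 72 without their replicates 1, 3 and 4 at 0 mg/kg/day. For Cyp2b-null females it was 82, 71 and 325 without replicates 2, 3 and 4 at 10 mg/kg/day and 36, 82 and 110 without replicates 2, 3 and 4 at 0 mg/kg/day. Without hCYP2B6-Tg female replicate 2 at 10 mg/kg/day Trim63 (1.81), Ddit4 (3.27) and Pdk4 (3.43) no longer passed, nor did Pdk4 without their replicate 1 at 0 mg/kg/day (4.52) or Trim63 by limma voom (1.71).

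The convergence of Amd1 and Cdk19 between the sexes led to the hypothesis that 10 mg/kg/day narrows sex differences more widely. To keep the choice of genes apart from the mice compared, 798 autosomal genes that differed between the sexes at 1 mg/kg/day were taken (435 higher in males, 363 higher in females). Signed by that difference, the median sex difference was 0.36 at 0 mg/kg/day, 0.57 at 1 mg/kg/day, where the genes were chosen, and 0.19 at 10 mg/kg/day. The median change from 0 to 10 mg/kg/day was -0.19 (permutation p = 0.00671, two-sided, 100000 permutations of dose within strata). The difference was smaller at 10 mg/kg/day in 628 of the 798 genes. Of these genes 11 passed the test of a sex difference in the effect. The test is in line with a narrowing, but was prompted by 2 genes of the same data, and a structure of the samples that was not identified stays open.

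Mice with high ubiquitin ligase transcripts at 10 mg/kg/day looked low in lipogenic ones, and the relation was tested over the 15 mice. The mean of the atrophy and FOXO list and that of the fatty acid synthesis list had r = -0.468 (permutation p = 0.0833) and rho = -0.468 (permutation p = 0.0819) pooled, and r = -0.45 without the 2 mice farthest from the median. Centred on each stratum, r was -0.227 (permutation p = 0.184) and rho -0.214 (permutation p = 0.458), with permutations within strata, two-sided. Then r was -0.0183 without the 2 farthest mice. Adjusted over the 2 relations computed, the p-values of r were 0.167 and 0.184. With 15 mice no relation was shown, and none can be excluded.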
